A study of Mus musculus with 6 samples.

How the data were processed

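RNA was measured by bulk mRNA sequencing in tumour-associated macrophages, the macrophages that settle inside a tumour, of the mouse. The labels place 6 libraries in 2 groups of 3. The KO libraries came from mice that carry floxed alleles of Trmt61a and LysM-Cre, a Cre recombinase expressed from the Lyz2 (lysozyme M) locus in myeloid cells. The WT libraries came from mice with the floxed alleles and without the Cre. MC38, a mouse colon carcinoma line, had been injected 14 days earlier, and the macrophages were collected by fluorescence-activated sorting. The sorting gate, the sex of the mice and the exons of Trmt61a that are floxed were not given in the sources used here. The labels number the replicates 1 to 3 in each group and do not say whether each came from its own mouse, so the p-values measure the spread between these libraries, which may be partly technical.

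Per the labels, RNA was extracted with a mirVana kit and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA. Trimmomatic, HISAT2, Cufflinks, HTSeq and the mouse build mm10 are named in the submitters' processing notes, without versions or roles. The deposited values are raw read counts per gene, whole numbers with totals that differ between libraries. The gene annotation, the strand setting of the counting and the treatment of reads that map to several genes were not given in the sources used here. Values of genes that overlap, have an antisense partner or have a near-identical copy are therefore uncertain.

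The deposited table held 21878 genes, of which 6323 had a count of 0 in all 6 libraries. None carried any of the 13 symbols of mitochondrially encoded genes that were looked for, spelled as in mt-Nd1. Other spellings were not searched. Totals ran from 18839026 to 20313597 counts per library. Coordinates were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, and 94.5% of the symbols matched it. Gene Ontology and KEGG terms were read from the deposited table itself.

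The comparison of KO with WT used edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed with filterByExpr (minimum count 10, minimum total 15), which left 12136 genes and 99.962% of the reads. Libraries were scaled by TMM factors, and a quasi-likelihood model with robust shrinkage was fitted with genotype as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are KO over WT. Levels are CPM, the counts of a gene relative to the TMM-scaled library total, given as mean ± SD of 3 libraries. A common biological coefficient of variation of 0.11 was estimated.

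A total of 35 lists were fixed: 26 of pathways, responses and gene groups and 9 of markers of other cell types that a sort of tumour macrophages could hold. Of these, 29 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom values. Camera asks whether the members of a list rank higher or lower than the other genes. Its correlation between members was preset at 0.01, and p-values were adjusted over the 29 lists. The same test was run over 3092 annotated terms of 10 to 300 tested genes. Each list and term was also tested with the correlation estimated from the data, and with fry, which asks whether the members move one way on balance without comparing them with other genes. Scores per library are the mean log2 CPM (prior count 2) of a list, centred over the 6 libraries. Sums and scores were compared with two-sided exact permutation tests, for which the smallest p with 3 libraries against 3 is 0.1.

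The groups, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names Trmt61a, Trmt6 and Lyz2 always. It then names up to 10 called genes in each direction with a mean of at least 1 CPM and KO values all on one side of the WT values. Where fewer than 5 pass, it names the 5 with the smallest p in that direction and says that they did not pass. Symbols of predicted genes, of the form Gm and digits or ending in Rik, were left out of that part. From each list it names up to 4 tested members with the smallest p, of which a few are not reported here. The 5 annotated terms with the smallest p in each direction were named. A few genes outside the rule are named in the closing section as chosen after their values were seen.

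Alternatives were RLE and upper-quartile factors, library totals alone, 3 other filters on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, edgeR without robust shrinkage, the replicate number as a block, other thresholds, and each library left out in turn. On counts simulated for the 12136 genes of this comparison, edgeR recovered 54.7% of genes changed 1.5-fold, 80.7% of those changed 2-fold and 96.5% of those changed 4-fold. Of its 161 calls 13 were false, and it made 0 calls where no gene had been changed. DESeq2 recovered 61.6%, 84.2% and 93.0% at the same folds, with 33 false calls among 187 and 5 calls where no gene had been changed. The simulation changed 86, 57 and 57 genes at these folds and drew each gene independently. Real genes can vary together, and with fewer changed genes the adjusted threshold is harder to pass. These rates are therefore not the power of the real comparison.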

Results

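Gene-level RNA counts were obtained for macrophages sorted from MC38 tumours, 3 libraries with Trmt61a deleted in myeloid cells (KO) and 3 without the deletion (WT). The totals were 19622763, 20247004 and 19743367 counts in WT and 18839026, 19391638 and 20313597 in KO, and the groups overlapped (exact permutation p = 0.5). Between 14037 and 14184 genes had reads in each library. Spearman correlations of log2 CPM were 0.9905 to 0.9963 between libraries of one group and 0.9883 to 0.9963 between groups, so the libraries did not separate by genotype on the whole transcriptome. KO replicate 2 stood farthest out on the first principal component, which held 32.0% of the variance, at 29.4 where the other libraries lay between -18.0 and 5.26. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was at least 7.70.

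Trmt61a encodes the catalytic subunit of the enzyme that makes m1A, a methylated adenosine, in tRNA. The study asks what its loss does to macrophages in a tumour, with interferon-associated genes as its focus. These libraries measure RNA levels and carry no measurement of translation. Trmt61a RNA (NCBI Gene 328162, chromosome 12, 111678105 to 111683902, plus strand, GRCm38) fell from 7.45 ± 0.532 CPM in WT to 2.11 ± 0.366 CPM in KO (SD, n = 3 each). Its counts were 157, 138 and 148 in the WT libraries and 41, 33 and 50 in the KO libraries. The log2 fold change was -1.81 (SE 0.197, edgeR adjusted p = 0.0426), so all 6 libraries followed their labels, and the KO level was 0.284 of the WT level. The deleted exons were not given in the sources used here, so this ratio covers the whole gene and is not a share of cells without the deletion. Trmt6, the partner subunit of the same enzyme, was at 30.6 ± 0.492 CPM in WT and 28.7 ± 0.487 CPM in KO and did not pass (log2 -0.095, SE 0.0771, edgeR adjusted p = 0.807). The call on Trmt61a held in 9 of 17 alternatives with log2 values from -1.94 to -1.69. It was lost without WT replicate 1 (adjusted p = 0.130), WT replicate 2 (0.0707), WT replicate 3 (0.314), KO replicate 1 (0.111) or KO replicate 3 (0.14).

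Across the transcriptome, 2 of 12136 genes passed, both lower in KO: Trmt61a and Ckb. Ckb encodes the brain-type creatine kinase, which passes phosphate between ATP and creatine. Its RNA (NCBI Gene 12709, chromosome 12, 111669361 to 111672338, minus strand) fell 5.54-fold, from 85.4 ± 25.2 to 15.4 ± 3.34 CPM (SD, n = 3 each; log2 -2.47, SE 0.236, edgeR adjusted p = 0.0426). Ckb and Trmt61a lie head to head, 5.77 kb apart. The 13 other tested genes within 500 kb of Trmt61a had a median log2 fold change of 0.029 and none passed, among them Bag5 on the far side of Trmt61a at -0.01 (SE 0.129) and Mark3 beyond Ckb at 0.029 (SE 0.0930). The call on Ckb held in 8 of 17 alternatives, with log2 values from -2.60 to -2.20 throughout and adjusted p values from 1.13e-29 with DESeq2 to 0.501 with no filter. It was lost without WT replicate 3 (0.294), KO replicate 1 (0.106), KO replicate 2 (0.395) or KO replicate 3 (0.285).

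**Figure D1:**
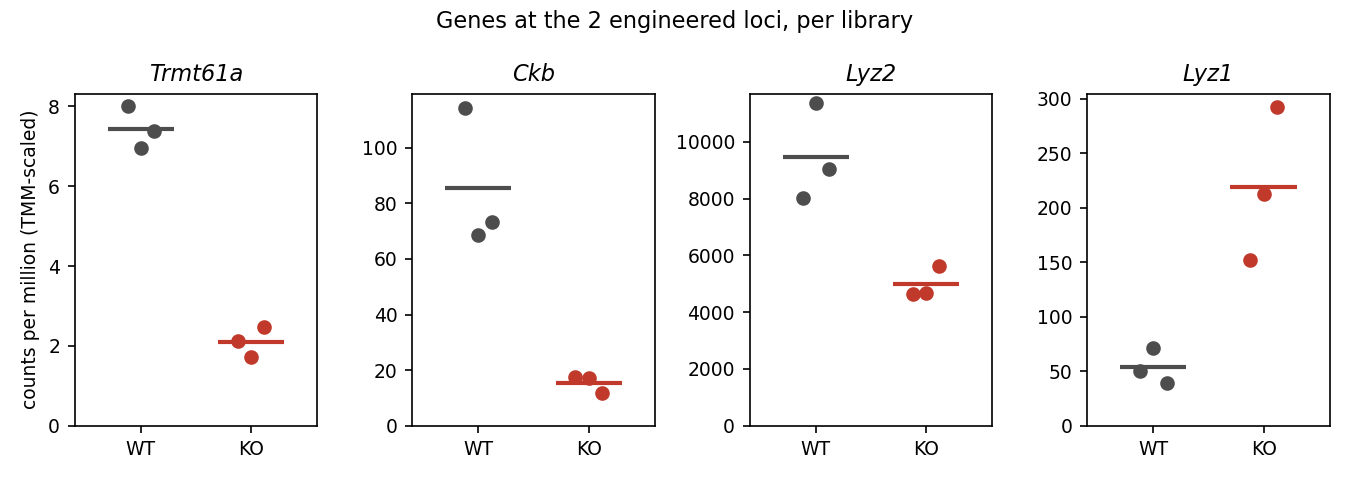
CPM (TMM-scaled, linear axes from 0) of Trmt61a, Ckb, Lyz2 and Lyz1 in each library, with WT in grey, KO in red and horizontal lines at the group means. Each gene's 3 KO values lie outside its 3 WT values, and the Ckb means are 85.4 CPM in WT and 15.4 CPM in KO.

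No gene passed as higher in KO with edgeR. At an unadjusted p under 0.05 there were 469 higher and 371 lower genes, 840 in all. The other 9 splits of the 6 libraries into 3 and 3, each of which mixes the genotypes, gave 185 to 1015 such genes. DESeq2 called 8 higher and 20 lower genes, limma-voom 0 higher and 1 lower, and limma-voom with quality weights 1 higher and 3 lower. Lyz2, the lysozyme of macrophages and the locus that carries the Cre, was at 9474 ± 1719 CPM in WT and 4990 ± 556 CPM in KO (chromosome 10, 117277331 to 117282321, minus strand; log2 -0.92, SE 0.135) and did not pass (edgeR adjusted p = 0.244). Lyz1, its close paralog 5.48 kb away, was at 53.7 ± 16.3 CPM in WT and 219 ± 70.4 CPM in KO (log2 2.03, SE 0.278) and did not pass either (edgeR adjusted p = 0.285). Both pass with DESeq2 (adjusted p = 9.22e-09 and 1.41e-04) and with quality weights (0.0452 and 0.0419). Reads of these near-identical genes can be divided between them in a way the counting does not record, so both values are uncertain. By p-value, Trmt61a, Ckb, Lyz2 and Lyz1 ranked 1 to 4 of the 12136 genes.

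The other genes with the smallest p in each direction did not pass. On the higher side were Rhov, an atypical small GTPase (log2 0.77, SE 0.138), Hspa1a, an inducible heat shock protein (0.62, SE 0.110), Cd24a, a surface glycoprotein (0.75, SE 0.146), and Sort1, the sorting receptor sortilin (0.51, SE 0.110). On the lower side were Zc3h12a, the RNase regnase-1 that degrades inflammatory mRNAs (log2 -0.56, SE 0.0985), and Vcam1, an adhesion molecule (-0.82, SE 0.155). Their edgeR adjusted p values were 0.438 for Rhov, Hspa1a and Zc3h12a and 0.694 for Cd24a, Sort1 and Vcam1. All of these except Sort1 pass with DESeq2. Hspa1a also passes with edgeR without WT replicate 2 (adjusted p = 0.0457). Of the 133 genes the rule names, 83 had a log2 value that moved by over 1.5 times when one library was left out. Trmt61a, Ckb, Lyz2 and Lyz1 were not among them, and most of the list members named hereafter were.

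**Figure D2:**
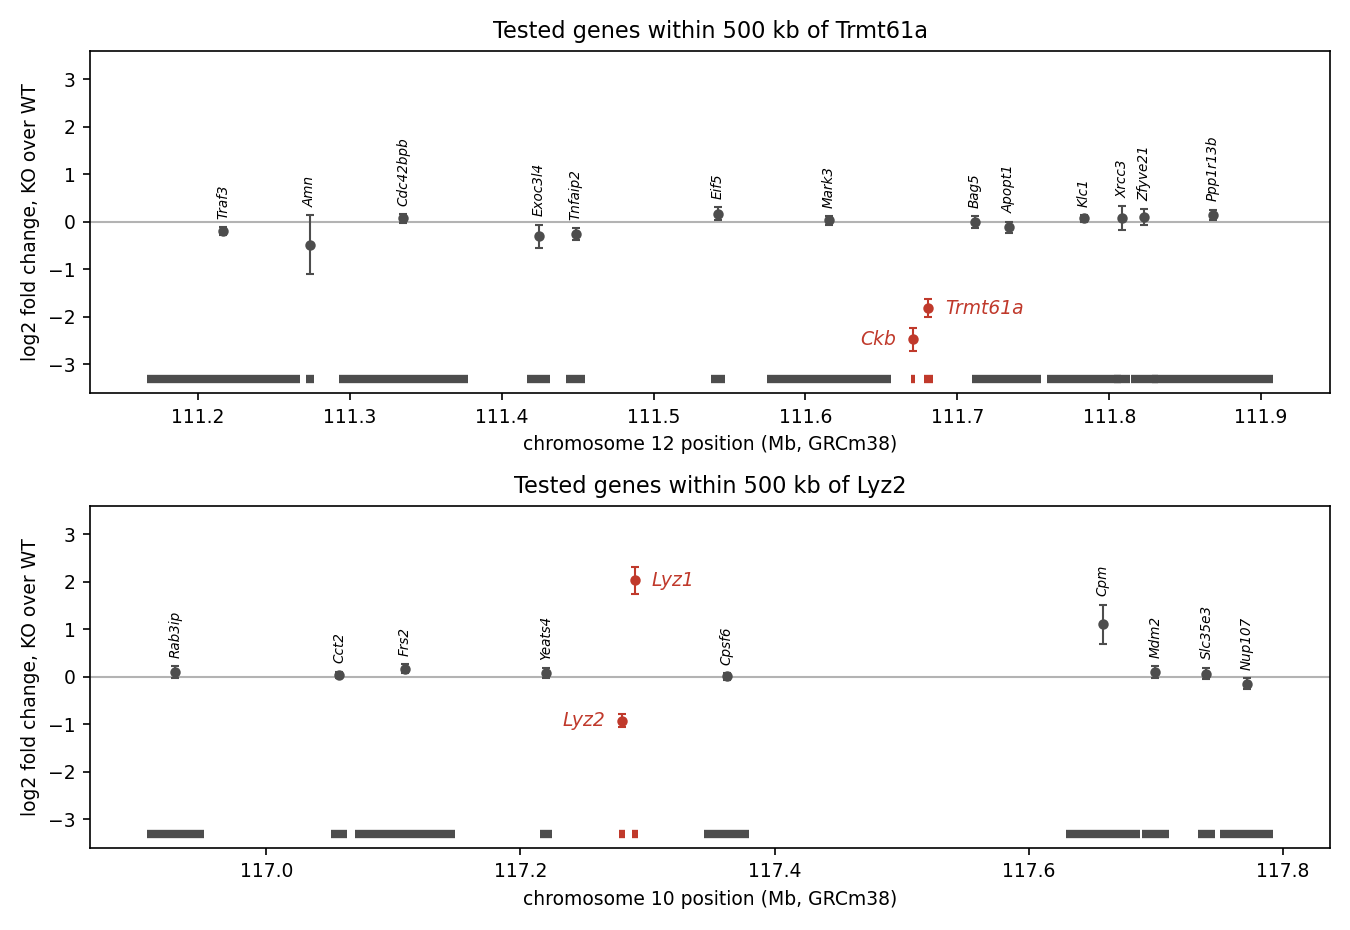
Log2 fold change of KO over WT (points, with SE bars) of tested genes within 500 kb of Trmt61a and of Lyz2, against GRCm38 position in Mb, with gene spans as bars at the foot. Ckb lies at -2.47 and Trmt61a at -1.81 on chromosome 12, where the other genes have a median of 0.029, and Lyz2 at -0.92, Lyz1 at 2.03 and Cpm at 1.10 on chromosome 10, where genes other than Lyz1 and Lyz2 have a median of 0.078.

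Interferon-associated genes ranked lower in KO as 3 lists with the preset correlation of camera, and no member passed by itself. With an estimated correlation no list was called (adjusted p = 0.847 for each). In the interferon gamma response, 26 of 28 tested genes had a negative log2 fold change, with a median of -0.44. Cxcl10 and Cxcl9, chemokines that attract T cells, had log2 values of -1.21 (SE 0.315; 383 ± 169 CPM in WT, 166 ± 39.8 in KO) and -0.54 (SE 0.193). Gbp5, a guanylate-binding protein of host defence, was at -1.02 (SE 0.306) and the GTPase gene Gm4951 at -0.60 (SE 0.219). In the type I interferon response, 30 of 32 genes were negative, with a median of -0.24. Its leading members were Ifi44 (-0.76, SE 0.312), Phf11d (-0.41, SE 0.136), Isg15, a ubiquitin-like modifier (-0.32, SE 0.133), and Bst2, the antiviral factor tetherin (-0.27, SE 0.0857). Of the receptors, sensors and signalling proteins of the interferon system, 17 of 22 were negative, with a median of -0.055. They include Mb21d1, the DNA sensor cGAS (-0.54, SE 0.144), Tmem173, its partner STING (-0.24, SE 0.109), Tlr9 (-0.46, SE 0.225) and Tlr3 (-0.27, SE 0.118).

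Camera with the preset correlation called the interferon gamma list (adjusted p = 3.96e-11), the type I list (1.84e-07) and the sensing list (0.0198) lower in KO. Adjusted over the list alone, 0 genes passed in any of the 3, as over all genes with edgeR. At an unadjusted p under 0.05, 7, 4 and 2 of their members were lower, and DESeq2 called 0. The interferon gamma score was 0.510, -0.042 and 0.194 in the WT libraries and -0.698, 0.105 and -0.069 in the KO libraries, so the groups overlapped (exact permutation p = 0.2). Without WT replicate 1, the log2 values were -0.80 for Cxcl10, -0.68 for Gbp5, -0.37 for Gm4951, -0.23 for Tlr9, -0.17 for Tlr3 and -0.12 for Tmem173. Without KO replicate 1 they were -0.34 for Cxcl9, -0.49 for Ifi44, -0.18 for Isg15 and -0.29 for Tlr9. The sensing list was lost without WT replicate 1 (0.301), KO replicate 1 (0.307) or KO replicate 3 (0.272).

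Antigen presentation genes also ranked lower in KO with the preset correlation of camera, but not with an estimated correlation (adjusted p = 0.847 for both lists). For MHC class I processing, 19 of 20 genes were negative with a median of -0.18, including the trimming peptidase Erap1 (-0.21, SE 0.0955), Tapbpl (-0.28, SE 0.126), the proteasome activator Psme2 (-0.25, SE 0.128) and the chaperone Calr (-0.18, SE 0.0949). For MHC class II, 9 of 12 were negative with a median of -0.12, including the peptide exchange factors H2-DMb1 (-0.27, SE 0.183) and H2-DMa (-0.20, SE 0.168), their transactivator Ciita (-0.35, SE 0.250) and the reductase Ifi30 (-0.091, SE 0.0866). No member passed over all genes, and 0 passed adjusted over the list alone with edgeR. DESeq2 called 0, and 1 class I gene and 0 class II genes had an unadjusted p under 0.05. Camera called both with the preset correlation (adjusted p = 3.25e-05 and 0.0360). Without WT replicate 1 the log2 values were -0.12 for Erap1, -0.18 for Tapbpl, -0.13 for Psme2 and -0.092 for Calr, and without KO replicate 1 they were -0.059 for H2-DMb1, -0.081 for Ciita, -0.0039 for H2-DMa and -0.018 for Ifi30. Without KO replicate 1 both calls were lost (0.498 and 0.126) and class II changed direction, and class II was also lost without WT replicate 2 (0.161). KO replicate 1 had the lowest MHC class II score (-0.666) and also the lowest sum of dendritic cell markers, 411 CPM against 550.4 to 661 CPM in the other libraries.

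Inflammatory activation genes ranked lower in KO with the preset correlation of camera (adjusted p = 8.99e-05) but not with an estimated correlation (adjusted p = 0.847). Of 24 members 16 were negative, with a median of -0.33. The score was 0.473, -0.015 and 0.109 in the WT libraries and -0.325, -0.107 and -0.135 in the KO libraries (exact permutation p = 0.1, the smallest the test allows). Cxcl1, a chemokine for neutrophils, was at 316 ± 41.8 CPM in WT and 176 ± 39.6 CPM in KO (log2 -0.84, SE 0.164). Il1a, a proinflammatory cytokine, was at 583 ± 119 and 376 ± 39.0 CPM (log2 -0.63, SE 0.142). Nlrp3, an inflammasome sensor, was at 1178 ± 161 and 877 ± 27.1 CPM (log2 -0.42, SE 0.0983). Il23a, a subunit of interleukin 23, was near the floor at 3.55 ± 2.86 and 0.664 ± 0.181 CPM (log2 -2.40, SE 0.630), and its log2 value was -1.54 without WT replicate 1. None passed over all genes with edgeR (adjusted p of 0.694 to 0.701), while 9 members lower and 2 higher passed adjusted over the list alone, and DESeq2 called 4 lower.

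Lists of proliferation, oxidative phosphorylation, ribosomal proteins and the unfolded protein response ranked lower with the preset correlation of camera. None was called with an estimated correlation (adjusted p = 0.847, 0.847, 0.963 and 0.847). All 30 proliferation genes were negative, with a median of -0.18, among them the cycling marker Mki67 (-0.34, SE 0.0776; 265 ± 20.8 CPM in WT, 208 ± 7.78 in KO), the topoisomerase Top2a (-0.30, SE 0.101), the spindle motor Kif11 (-0.23, SE 0.0902) and the helicase subunit Mcm3 (-0.23, SE 0.0885). Of oxidative phosphorylation genes 29 of 30 were negative, with a median of -0.10, including Sdhb (-0.17, SE 0.0867), Cs (-0.11, SE 0.0671), Atp5c1 (-0.11, SE 0.0690) and Uqcrb (-0.15, SE 0.0989). Of cytosolic ribosomal proteins 33 of 35 were negative, with a median of -0.048 and Rps6 at -0.12 (SE 0.0888), Rpl13a at -0.089 and Rps18 at -0.10. In the unfolded protein response 16 of 19 were negative, with a median of -0.097. Its members with the smallest p went both ways, with the chaperones Canx (-0.17, SE 0.0731) and Hsp90b1 (-0.18, SE 0.0849) negative and Dnajb9 (0.29, SE 0.0766) and the ubiquitin ligase Syvn1 (0.23, SE 0.119) positive.

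No gene of these 4 lists passed over all genes. Adjusted over the list alone, 1 proliferation gene passed as lower and 0 genes of the other 3 lists with edgeR, and DESeq2 called 0 in each. At an unadjusted p under 0.05, 9 proliferation genes were lower, 1 unfolded protein response gene was lower and 1 higher, and 0 were in the other 2 lists. Camera with the preset correlation called proliferation (adjusted p = 1.50e-11), oxidative phosphorylation (3.36e-05), ribosomal proteins (0.0263) and the unfolded protein response (0.0326) lower. Ribosomal proteins were lost without WT replicate 2 (0.724, with the direction changed), KO replicate 1 (0.588) or KO replicate 2 (0.611), and the unfolded protein response without WT replicate 1 (0.787) or KO replicate 1 (0.498).

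Stress-responsive genes ranked higher in KO with the preset correlation of camera, and not with an estimated correlation (adjusted p = 0.602 for immediate early genes and 0.847 for the integrated stress response). Among immediate early and dissociation stress genes, which respond within minutes to handling and to tissue digestion, 20 of 23 were positive with a median of 0.22. Their score was -0.241, 0.03 and -0.125 in the WT libraries and 0.06, 0.137 and 0.139 in the KO libraries (exact permutation p = 0.1, the smallest the test allows). Hspa1a was at 103 ± 17.3 CPM in WT and 159 ± 6.39 CPM in KO, and Hspa1b at 113 ± 22.1 and 173 ± 23.1 CPM. The transcription factors Jun and Klf2 had log2 values of 0.39 (SE 0.106) and 0.47 (SE 0.142). In the integrated stress response 17 of 21 were positive with a median of 0.12, including Ddit4, an inhibitor of mTORC1 (0.41, SE 0.0948), and the transcription factors Atf4 (0.26, SE 0.0742) and Atf3 (0.39, SE 0.144), with Sesn2 at 0.20 (SE 0.0987). No member passed over all genes with edgeR, and adjusted over the list alone 3 and 1 passed as higher. DESeq2 called 2 and 0, and 9 and 3 were higher at an unadjusted p under 0.05. Camera with the preset correlation called both (adjusted p = 4.08e-09 and 0.00374), and the integrated stress response was lost without KO replicate 3 (0.589).

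**Figure D3:**
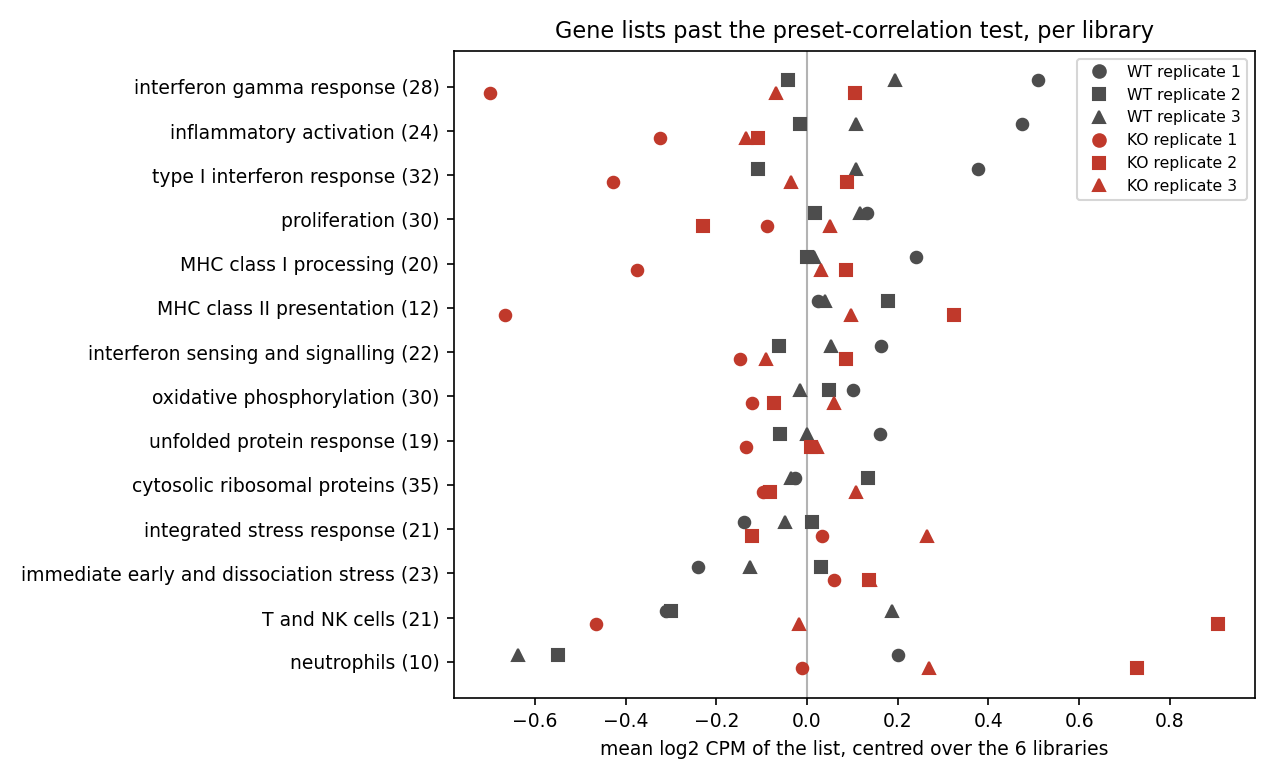
Mean log2 CPM of each list that passed camera with the preset correlation, centred over the 6 libraries, with WT in grey, KO in red, 1 symbol per library and the number of tested genes in brackets. The genotypes overlap in most lists, and the T and NK cell score of 0.907 and the interferon gamma score of -0.698 each belong to one KO library.

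Markers of other cells were also compared, since a sort can carry them over. Macrophage identity genes summed to 14425 ± 621 CPM in WT and 14515 ± 363 CPM in KO (exact permutation p = 0.8). Neutrophil markers summed to 157 ± 17.2 CPM and 219 ± 27.3 CPM (p = 0.1, the smallest the exact test allows). Their score was 0.2, -0.549 and -0.638 in the WT libraries and -0.012, 0.727 and 0.27 in the KO libraries. By score the groups therefore overlapped (exact permutation p = 0.2). Of 10 tested neutrophil markers 8 were positive with a median of 0.62, among them the granule and protease genes Ltf (1.87, SE 0.487; under 1 CPM in both groups), Mmp8 (0.55, SE 0.190) and Mmp9 (39.5 ± 8.48 CPM in WT, 78.9 ± 41.1 in KO), and S100a8 (0.69, SE 0.297). Mmp9 was at 125 CPM in KO replicate 1, a large part of the neutrophil sum of 241 CPM there. It was at 46.8 and 64.8 CPM in KO replicates 2 and 3. Its log2 value was 0.497 without KO replicate 1. Whether the neutrophil sums separate without Mmp9 was not tested. Markers of T and NK cells summed to 207 ± 23.1 CPM and 256 ± 62.7 CPM (exact permutation p = 0.3), with KO replicate 2 highest at 326 CPM. Most of this sum was Il7r, at 132 ± 17.5 CPM in WT and 161 ± 15.2 CPM in KO. Of 21 tested, 19 were positive with a median of 0.34, including Il7r (0.29, SE 0.107), Cd28 (0.88, SE 0.385), Cd2 (0.98, SE 0.425) and Foxp3 (0.80, SE 0.399). Without KO replicate 2 these 3 were at 0.38, 0.34 and 0.46, and S100a8 was at 0.33. Camera with the preset correlation called neutrophil markers (adjusted p = 7.68e-04) and T and NK markers (0.0136) higher in KO, and neither with an estimated correlation (adjusted p = 0.602 and 0.847). No marker passed over all genes, and adjusted over the list alone 1 neutrophil marker and 0 T and NK markers passed with edgeR. At an unadjusted p under 0.05, 4 and 3 were higher, and DESeq2 called 0. The T and NK call was lost without WT replicate 1 (0.0625), WT replicate 2 (0.160) or KO replicate 2 (0.738), where the direction also changed.

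Sums for other markers, in WT and KO, were 601 ± 56.1 and 509.8 ± 85.7 CPM for dendritic cells, 342 ± 76.2 and 336 ± 52.7 CPM for fibroblasts, and 81.8 ± 3.67 and 89.9 ± 4.19 CPM for endothelial cells (exact permutation p = 0.3, 1 and 0.1). They were 120.5 ± 35.0 and 127 ± 12.6 CPM for tumour epithelium, 4.98 ± 0.777 and 7.91 ± 2.99 CPM for mast cells, basophils and eosinophils, 2.50 ± 0.311 and 3.29 ± 0.937 CPM for B and plasma cells, and 0.184 ± 0.143 and 0.557 ± 0.485 CPM for erythroid cells (exact permutation p = 0.9, 0.2, 0.4 and 0.4). The exact permutation p of 0.1 for endothelial cells is the smallest the test allows. Most of the endothelial sum was Pecam1, at 53.9 ± 6.83 CPM in WT and 63.1 ± 9.07 CPM in KO. Of 6 tested endothelial markers 2 were positive and 4 negative. Most of the tumour epithelium sum was Cdh1, at 115 ± 34.0 CPM in WT and 121 ± 11.7 CPM in KO. Y-linked genes were read in all 6 libraries and summed to 171 ± 9.57 and 185 ± 18.5 CPM. Camera did not call dendritic cell (adjusted p = 0.143), fibroblast (0.968) or endothelial (0.968) markers, and the others had fewer than 5 tested members. Dendritic cell markers passed as lower without WT replicate 2 (0.0227) or KO replicate 2 (0.0139).

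Several lists of macrophage states did not pass camera. Alternative activation had 11 of 20 members positive (adjusted p = 0.968), with Il10 at -1.06 (SE 0.393; -0.48 without WT replicate 1), Klf4 at 0.54 (0.27 without WT replicate 1), Ccl17 at 0.64 (0.22 without KO replicate 2) and Pdcd1lg2 at -0.46 (-0.17 without KO replicate 1). Lipid-associated and complement genes had 12 of 22 positive (0.903), with Gpnmb at 0.38 and Ctsl at 0.32 but C1qc at -0.25 and C1qa at -0.21. Checkpoint genes had 7 of 14 positive (0.989), with Siglec1 at -0.39, Cd276 at 0.33 and Lilrb4a at 0.25. Monocyte genes had 8 of 16 positive (0.806), with the fractalkine receptor Cx3cr1 at -0.54 (SE 0.127), which passed adjusted over the list alone and with DESeq2 over all genes (adjusted p = 0.0297), Nr4a1 at 0.20, Vcan at 0.43 and Itgal at -0.20. Macrophage identity genes had 6 of 16 positive (0.968), with the transcription factors Cebpb at 0.31 and Cebpa at 0.40, and Mpeg1 at -0.22.

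Hypoxia and glycolysis genes had 17 of 24 positive (adjusted p = 0.143 by camera), with Hk2 at -0.31, Pfkfb3 at 0.23, Vegfa at 0.19 and Egln3 at 0.30. Cholesterol synthesis had 7 of 20 positive (0.695), with Idi1 at -0.30, Dhcr7 at -0.18, Lss at -0.23 and Fdps at -0.19. Lysosome and phagocytosis genes had 13 of 26 positive (0.968), with Cd300lf at 0.27 and Fcgr4 at -0.40. Nucleolar genes and Myc targets had 7 of 22 positive (0.255), with Ppan at 0.20, Nolc1 at -0.14, Nop58 at -0.16 and Gnl3 at 0.13. Cytosolic tRNA synthetases had 7 of 20 positive (0.333), with Cars at 0.13, Kars at -0.12, Farsb at -0.10 and Rars at -0.091. In the tRNA and m1A modification list 11 of 22 were positive (0.494), Trmt61a was the only call over all genes and adjusted over the list alone, and Adat3 (0.64), Alkbh1 (0.26) and Trmt10b (-0.34) did not pass. The fixed list of genes neighbouring Lyz2 had 10 of 16 positive (0.171), with Cpm at 1.10 (SE 0.415), Rap1b at -0.16 and Frs2 at 0.17, and Lyz1 passed adjusted over the list alone. Adjusted over the list alone, 0 genes passed in the other lists of these groups with edgeR. At an unadjusted p under 0.05 each of those lists had at most 3 higher and 2 lower members, and DESeq2 called 0. Of these lists, 3 passed without one library: hypoxia and glycolysis without WT replicate 2 (2.55e-04), cholesterol synthesis without WT replicate 1 (1.87e-06) and tRNA synthetases without KO replicate 3 (0.00878). The median, mean and test differed in sign for alternative activation, checkpoint, monocyte, macrophage identity, dendritic cell and fibroblast lists.

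Among the annotated terms, 48 ranked lower and 6 higher in KO by camera with the preset correlation. None of the 3092 terms was called with an estimated correlation (adjusted p = 0.973 for each named term) or by fry (lowest adjusted p = 0.654). The lower ones with the smallest p were cellular response to interferon-beta (34 of 37 genes negative, median log2 -0.33, adjusted p = 4.15e-06), DNA replication (32 of 35, -0.15, 5.40e-05), proteasome (41 of 44, -0.10, 3.43e-04) and ribosome, as a Gene Ontology term (144 of 171, -0.062, 0.00167) and as a KEGG pathway (116 of 131, -0.057, 0.00205). The higher ones were cellular response to fibroblast growth factor (10 of 12 positive, adjusted p = 0.0220), inflammatory leukocyte migration (8 of 10, 0.0284), nuclear receptor activity (21 of 26, 0.0403), response to osmotic stress (11 of 12, 0.0441) and negative regulation of protein kinase B signalling (26 of 31, 0.0443). Proteasome was lost without WT replicate 1 (0.214) or KO replicate 1 (0.0979), ribosome as a Gene Ontology term without WT replicate 2 (0.182), KO replicate 1 (0.318) or KO replicate 2 (0.159), and as a KEGG pathway without the same libraries (0.517, 0.420 and 0.267). The fibroblast growth factor term was lost without WT replicate 1 (0.106), WT replicate 3 (0.0603) or KO replicate 1 (0.0765), and leukocyte migration without WT replicate 3 (0.202), KO replicate 1 (0.0765) or KO replicate 3 (0.241). Nuclear receptor activity was lost without WT replicate 1 (0.375), WT replicate 3 (0.0733), KO replicate 1 (0.186) or KO replicate 2 (0.195). Osmotic stress was lost without WT replicate 1 (0.0502), WT replicate 2 (0.136), KO replicate 1 (0.216) or KO replicate 2 (0.381), and protein kinase B signalling without WT replicate 1 (0.208), WT replicate 3 (0.0998), KO replicate 1 (0.211) or KO replicate 3 (0.0753). The count of lower terms was 20 without WT replicate 1, 2 without KO replicate 1, 82 without KO replicate 2 and 90 without KO replicate 3. The count of higher terms was 2, 0, 22 and 12 without the same libraries, and 11 without WT replicate 2.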

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

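All alternatives had been chosen before the results were seen, and 1 choice was changed at a time except with DESeq2. DESeq2 was run on the unfiltered counts with its own size factors and tested 15555 genes. Its difference from the main result is therefore not that of the test alone. Trmt61a kept its direction under all 17 alternatives. Its call was lost with a filter on a mean of at least 1 CPM (log2 -1.81, adjusted p = 0.0583) and with limma-voom (log2 -1.82, adjusted p = 0.0522), and leaving out each library in turn gave log2 values from -1.94 to -1.69 and a call only without KO replicate 2, with fewer samples behind each fit. Genes lower in KO numbered 1 with RLE factors, 1 with upper-quartile factors, 1 with library totals alone, 1 with no filter, 0 with the filter on mean CPM, 20 with DESeq2 on unfiltered counts, 1 with limma-voom and 0 to 2 with each library left out, against 2. Genes higher in KO numbered 8 with DESeq2, 1 with quality weights and 0 to 3 with each library left out, against 0. An adjusted p under 0.1, or a change of at least 2-fold added to the threshold, left both counts at 2 and 0. The lost call was Ckb with RLE factors (adjusted p = 0.0517), upper-quartile factors (0.128), library totals (0.128) and no filter (0.501), where its log2 value stayed at -2.47. Why the calls moved while the fold changes did not was not tested. No pairing by replicate number was seen, since same-numbered libraries deviated from their group means with correlations of -0.057, -0.094 and -0.109 and none correlated best with its own number. The deviations of 3 libraries from their mean are tied to each other, so this does not settle whether the libraries were paired. With the replicate number as a block Ckb alone was called, so 1 gene was lower, and Trmt61a had a log2 value of -1.82 (adjusted p = 0.103). The block left the count of called lists at 10 lower and 4 higher. Lists lower in KO numbered 0 with the estimated correlation, 0 with fry and 5 to 10 with each library left out, and lists higher in KO 0, 0 and 3 to 4. Annotated terms lower in KO numbered 0, 0 and 2 to 90, and terms higher in KO 0, 0 and 0 to 22. Of the 131 named genes other than Trmt61a and Ckb, 11 changed direction under an alternative, none of them past the threshold there. With each library left out, log2 values ran from -0.012 to 0.21 for Ddx3y, -0.15 to 0.53 for Cd79b, -0.11 to 0.77 for Thy1, -0.20 to 0.0235 for Col5a1, -0.59 to 0.090 for Col1a1, -0.074 to 0.33 for Vwf, -0.86 to 0.14 for Kdr, -0.47 to 0.28 for Flt1, -0.15 to 0.25 for Cdh1, -0.21 to 0.73 for Kit and -0.63 to 0.013 for Ccr3. With quality weights Cdh1 was at -0.0079 and Kit at -0.0185. Lists whose direction changed without some library had camera adjusted p values from 4.97e-06 to 0.161 for MHC class II, 1.04e-06 to 0.724 for ribosomal proteins, 6.27e-08 to 0.738 for T and NK cells, 1.87e-06 to 0.891 for cholesterol synthesis, 0.00878 to 0.802 for tRNA synthetases, 0.464 to 0.821 for alternative activation, 0.188 to 0.889 for lipid-associated genes, 0.546 to 0.891 for checkpoint genes, 0.172 to 0.924 for monocyte genes, 0.301 to 0.970 for macrophage identity, 0.470 to 0.970 for lysosome genes, 0.492 to 0.842 for fibroblasts and 0.667 to 0.993 for endothelial cells. The direction also changed for alternative activation with fry (0.960), with at least 10 reads in every library (0.979) and with the replicate block (0.945), for checkpoint genes (0.979) and endothelial cells (0.961) with at least 10 reads in every library, and for fibroblasts (0.910) and endothelial cells (0.910) with the replicate block. The cause of these changes was not tested. Among all comparisons of a named gene other than Trmt61a with an alternative, 2195 kept direction and side, 17 gained a call, 9 lost the call on Ckb and 15 changed direction. For lists these were 242 kept, 5 gained, 40 lost and 32 changed, and for named terms 63 kept and 46 lost. Depth limits the genes near the floor: the 12136 tested genes hold 99.962% of the reads, and the 9742 others stayed out of the main comparison, with 15555 genes tested where no filter was applied.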

Other observations

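The tests of the neighbourhood of Trmt61a, of shared reads and the Cre allele at Lyz2, and of how list members vary together were chosen only after those results were seen. The genes below that lie outside the rule for named genes were chosen after their values were seen.

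DESeq2 called 28 genes, the 2 of edgeR among them. Lower in KO were Tnip3, an inhibitor of NF-kappaB signalling (143 ± 19.0 CPM in WT, 79.6 ± 19.4 in KO; DESeq2 adjusted p = 5.63e-04), Zc3h12c, a relative of regnase-1 (44.4 ± 14.9 and 22.9 ± 1.71 CPM; 0.00396), the tissue factor gene F3 (27.4 ± 9.01 and 14.8 ± 1.54 CPM; 0.0180), the receptor Tlr2 (872 ± 100.1 and 649 ± 51.4 CPM; 0.0255), the activation marker Cd83 (548 ± 78.4 and 345 ± 75.3 CPM; 0.0142) and Ccrl2, an atypical chemokine receptor (630.1 ± 159 and 386 ± 66.8 CPM; 0.0148). Higher in KO were Txnip, a thioredoxin inhibitor (129.9 ± 13.5 and 173 ± 11.98 CPM; 0.0401), the metalloproteinase Mmp19 (249 ± 72.2 and 402 ± 35.0 CPM; 0.0368) and the phospholipase Pla1a (4.17 ± 0.605 and 8.83 ± 2.62 CPM; 0.0297). None of these 9 genes passed with edgeR on all 6 libraries, where their adjusted p values were 0.694 or 0.701. Without KO replicate 2 edgeR called Pla1a, Vcan, Cxcl3, Gm39972 and Trmt61a. On simulated counts of 12136 genes with no changed gene DESeq2 made 5 calls and edgeR 0. With changed genes 33 of the 187 calls of DESeq2 were false. The 28 calls on the real counts came from 15555 tested genes, so the simulated counts cover a smaller set of genes.

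The count of called genes was 2 for the real grouping. It was 0 for each of the 9 other splits of the 6 libraries into 3 and 3. Thus 1 of 10 splits gave as many. The called genes were the deleted gene, Trmt61a, and its neighbour Ckb, whose WT and KO levels did not overlap. Every other split puts both genotypes on each side and could hardly call them, so this count says little about chance. For the 29 lists, 14 were called by camera with the preset correlation and the highest of the other splits called 14, with 4 of 10 splits giving as many. For annotated terms the real grouping called 54 and the highest other split 177, with 6 of 10 splits giving as many. In this exact enumeration the unadjusted camera p of the interferon gamma list was 2.73e-12 for the real grouping and 3.74e-22 for the lowest of the others, with 4 of 10 splits as small. For proliferation the camera p was 5.17e-13 for the real grouping and 4.20e-16 for the lowest of the others. For immediate early genes these were 4.22e-10 and 1.55e-09. The 10 splits are too few for a share under 0.05. Every split but the real one mixes the genotypes in unequal shares, so a difference by genotype is partly kept in it. The results of the other splits are therefore not a chance level. The split with 177 terms set WT replicates 1 and 3 and KO replicate 2 against the rest, and called 0 genes with edgeR (771 at an unadjusted p under 0.05, against 840 for the real grouping).

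Ckb fell 5.54-fold beside the deleted gene. Its loss of 70.0 CPM exceeded the WT level of Trmt61a, 7.45 ± 0.532 CPM. That alone does not settle whether reads of Trmt61a were counted as Ckb, since such reads would be missing from the Trmt61a level. In GENCODE M21 the genes lie 5.77 kb apart on opposite strands and do not overlap, which argues against such miscounting. The annotation used for the counting was not given. A shift of the whole neighbourhood is argued against by the median log2 value of 0.029 of the 13 other tested genes within 500 kb. An effect of the recombined allele on the adjacent gene stays open as a candidate explanation, raised by the position of Ckb; the probability that a random tested gene flanks Trmt61a, 1.65e-04, restates that position and tests nothing further. It cannot be told apart from an effect of losing the enzyme or of the Cre on Ckb RNA. Every KO library carries the recombined allele, the loss and the Cre, and no WT library carries the Cre.

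Lyz2 was lower and Lyz1 higher in KO, neither past the threshold with edgeR. Shared reads that follow Lyz2 would lower Lyz1 as well, and its log2 value was 2.03 (SE 0.278), which argues against them as the whole cause. A Cre inserted at Lyz2 may lower its RNA, and the KO level was 0.527 of the WT level, but the Cre is present in every KO library and in no WT library. The Cre allele, sequence variants linked to it and the deletion of Trmt61a therefore cannot be told apart for Lyz2 and Lyz1. The 9 tested genes within 500 kb of Lyz2 besides Lyz1 had a median log2 value of 0.078, and none passed.

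The interferon gamma list ranked lower in KO with the preset correlation (camera adjusted p = 3.96e-11). WT replicate 1 had the highest score, and without it the adjusted p was 3.14e-08. Passing without it decides nothing about that library, since 7 of the 9 other splits also passed camera with the preset correlation, in either direction. Those splits of all 6 libraries mix the genotypes in unequal shares, so a difference by genotype could pass in them too. The scores were 0.510 in WT replicate 1 and -0.698 in KO replicate 1. They were -0.042 and 0.194 in the other WT libraries and 0.105 and -0.069 in the other KO libraries. The gap between the groups thus lay largely in WT replicate 1 and KO replicate 1, and the share of each was not tested. Without KO replicate 1, which had the lowest score, the camera adjusted p was 1.52e-04. Over the libraries left out in turn it ran from 2.49e-21 to 1.52e-04. The members varied together between libraries, with an estimated correlation of 0.837, and with it the camera adjusted p was 0.847. A shared swing of these genes between single libraries therefore remains a candidate explanation for the call. An effect of the deletion or of the Cre allele also stays open. The deletion and the Cre cannot be told apart, because they go together in every KO library.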
